A study of Mus musculus with 2 samples.

How the data were processed

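The series holds 2 samples of mouse RNA, each hybridised to 1 array of a bead chip. The ES sample is labelled day 0 and the EB sample day 4. The labels do not spell out either abbreviation; in stem cell work they usually stand for embryonic stem cells and embryoid bodies, the aggregates in which such cells differentiate. With 1 sample per group there was no replicate, so no test, p-value or standard deviation across samples was computed, and culture, array position and group cannot be told apart. Per the labels, total RNA was purified on a spin column and labelled with biotin by the array maker's procedure. The genome build of the array's annotation is not given in the sources used here.

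The signal intensity of each probe is the mean over its beads, read per the file headers in BeadStudio 2.3.41 with normalization set to none and no background step named. The sample titles call the data normalised, which by those headers does not hold for the sample files. The submitters' processing notes also name BeadStudio 2, RMA and limma, without saying what each was used for. Both arrays carry 46643 probes. The deposited spread between beads was tested against the number of beads: its slope on log scales was -0.44 in ES and -0.47 in EB for signals of at least 1000, where a standard error would give -0.5 and a standard deviation 0. It was therefore read as a standard error of the bead mean, and the bead-level standard error given beside log2 differences covers measurement within an array and no biological variation. The deposited detection score, which runs from 0 to 1 with 1 for bright probes, was found in the EB file alone.

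The series value table was set against the sample files. Within each array it rose with the signal over all probes, with a Spearman correlation of 1 and 0 decreases, and its sorted columns differed by at most 15.3 signal units. Its medians were 16.7 in both arrays, against 173.9 and 173.3 in the sample files, while the brightest percent of probes kept a ratio of 1.01 in ES and 0.97 in EB. The table thus holds linear intensity, close to quantile normalized and with the low end stretched downward. How the authors made it is not stated, so it served as an alternative.

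For the main values the deposited intensities were quantile normalized over both arrays and put on the log2 scale, without background subtraction, because the headers name neither step. That differs from the usual normexp background correction for such arrays, which was run as an alternative chosen after the data were seen (limma 3.58.1 in R 4.3.3, offset 50). Unsubtracted background shrinks the differences of dim probes. A probe counted as detected in EB at a detection score above 0.99 and in ES, for want of a score, at a signal above that array's median of 173.9, which is the looser condition. The score limit corresponded to a raw EB signal of 225.7 and a normalized signal of 230.0, called the signal floor here. Where the dimmer of the 2 signals lay under the floor, the ratio is given as "at least", against the floor, and where both did no ratio is given. Such bounds can be smaller than 2-fold although the gene passed the size rule on its measured signals.

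The files hold no gene symbols. Zero-padded numbers of at least 10000 inside the target identifiers were read as NCBI Gene numbers and looked up in a RefSeq gene table of assembly GRCm38.p6, used for names and not for coordinates. Of 11857 such probes 9796 (82.6%) matched, against 22.9% when the numbers were shifted, while numbers without padding matched no better than shifted ones (10.6% against 11.0%) and were left unnamed. The reading was checked on the signals. Of 89 probes named as ribosomal protein genes 77 lay above the floor in ES, and of 343 named as olfactory receptors 0 did. Over 451 genes with 2 probes above the floor in at least 1 array the differences of the 2 probes correlated at r = 0.83 across genes, which are not independent replicates, and the highest of 1000 shuffled pairings gave 0.15. The difference between 2 such probes had a standard deviation of 0.39 on the log2 scale. Of 44 such genes whose first probe passed the size rule described below, all 44 second probes had the same sign and 21 passed it. A further 20 probes were named by RefSeq accession. In all 9816 probes (21.0%) of 8106 genes were named and 36827 were not, so the counts cover part of the array. Pou5f1, T, Fgf5, Sox17, Kdr and Sox1 were not among the named genes and are not analysed here.

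One probe stood for each gene, that with the highest mean log2 signal. A gene counted as higher or lower at an absolute log2 difference, EB minus ES, of at least 1, if detected in at least 1 sample. The 28 gene lists (581 entries), this rule, the rule for named genes and most of the other settings were fixed before the data were examined. The text names the 12 genes with the largest differences in each direction, up to 4 members of each list past the size rule, and a preset group of markers, except that some genes are not reported here; other genes it names are list members chosen after their values were seen. A list's median difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins, and stood apart at a percentile under 2.5 or over 97.5, as a description of these 2 arrays. Lists with under 5 detected genes were given as counts. Signals under the floor entered list medians and the choice of named genes as measured, so such genes have no fixed rank. Alternatives covered the normalization, background, source of values, detection filter, pseudocount, probe choice, size rule and list statistic. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

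The steps were tested on simulated data for this comparison over 5187 genes, with 200 genes changed and unsubtracted background kept. At a simulated 2-fold change 15 of 200 (7.5%) passed the size rule, at 4-fold 146 of 200 (73.0%), and 0 of 4987 unchanged genes passed in either run. In these runs both arrays were drawn from the ES array with bead-level noise alone. They hold no variation between arrays or cultures, so the 0 is no false-positive rate for the measured genes. Of 200 simulated lists without a shift 11 (5.5%) stood apart, and of 100 lists shifted by 1 on the log2 scale all 100 did. The simulated 2-fold change lies at the limit of the size rule, and the kept background pulls it under that limit. Its low recovery was thus set by construction and gives no rate for larger changes. At 4-fold all 78 changed genes with an ES signal of at least 1000 passed, so the changes missed there were in dimmer genes.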

Results

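Transcript levels were compared between mouse ES cells at day 0 and EB cells at day 4, with 1 bead array per sample. Per the labels, the arrays served for comparison with sequencing of the same samples, which is not analysed here. A median of 38 beads lay behind each signal in ES and 37 in EB. The median signal before normalization was 173.9 in ES and 173.3 in EB. After quantile normalization 13240 (28.4%) and 13243 (28.4%) of 46643 probes exceeded the signal floor. These counts are nearly equal by construction, because both arrays then share 1 distribution and 1 floor. Above the floor the median bead-level error was 4.49% and 4.39% of the signal. There were no replicates, so every difference below describes these 2 arrays, and the errors cover beads within an array only. The number of arrays limits the precision.

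The comparison asked which transcripts differed between undifferentiated and differentiating cells. Of 5187 detected named genes, 144 were higher and 207 lower in EB by the 2-fold size rule, and 23 and 40 of these exceeded 4-fold (a log2 difference of at least 2). Of the 12 genes with the largest measured differences on the lower side 6 belonged to the pluripotency list, and the 12 on the higher side included the developmental regulators Lhx1, Hoxb2, Lmo2 and Eomes. The dimmer signal was under the floor in 41 of the higher and 73 of the lower genes. Signals correlated across genes, which are not independent replicates, at a Pearson r of 0.95 and a Spearman correlation of 0.91. The median difference was 0.0015, with quartiles of -0.23 and 0.25. From the series value table's signals 546 were higher and 577 lower by the 2-fold rule. With the main values and a 1.5-fold rule 479 were higher and 471 lower. In the main values lower genes were thus in excess at the 2-fold but not at the 1.5-fold limit. Over all 23457 detected probes, named or not, 502 were higher and 784 lower.

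**Figure D1:**
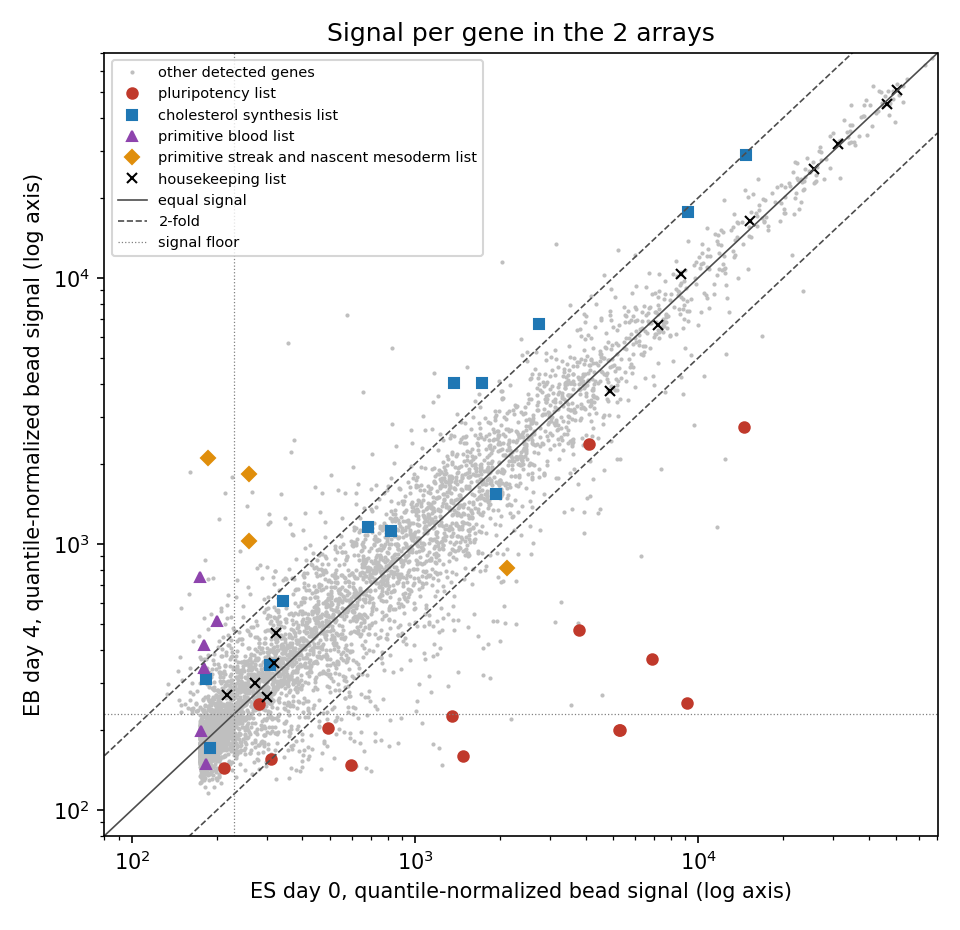
Quantile-normalized bead signal of each detected named gene in ES day 0 (x axis) and EB day 4 (y axis), both on log axes, with 1 array per sample. Colours mark members of 5 gene lists, dashed lines a 2-fold difference and dotted lines the signal floor of 230.0; all 14 pluripotency genes lie below the line of equal signal.

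The pluripotency list had the largest shift of the lists given a percentile. All 14 of its detected members had a negative difference and 10 were lower past the size rule, with a median log2 difference of -2.49 (percentile 0 of the matched random lists, which held 95% of their medians between -0.23 and 0.30). The median was -2.47 with signals set to the floor and -4.15 with the values of the series table. Klf2, a transcription factor of naive pluripotency (identifier scl016598.3_26-S), had a signal of 9100 in ES and 252 in EB, 36.2-fold lower, with a log2 difference of -5.18 and a bead-level standard error of 0.09. The EB signal of Klf2 lay just over the floor, and with the values of the series table its log2 difference was -7.02. Zfp42, a marker of undifferentiated ES cells, was at least 22.8-fold lower and Spp1, the secreted phosphoprotein osteopontin, at least 23.0-fold lower. Dppa4 was 18.6-fold lower by its brighter probe, and its second probe gave a smaller log2 difference (-3.08 against -4.22). Dppa3 was at least 6.42-fold lower, and Klf5 had signals of 3792 in ES and 474 in EB. Nanog, a core pluripotency factor, was 5.26-fold lower (signals of 14530 and 2760), and its 3 probes gave log2 differences of -2.40, -2.49 and -2.03. Sox2 was at least 2.14-fold lower. Of the members under the size rule, Tdgf1 had a log2 difference of -0.17. Its signals of 282 in ES and 251 in EB lay just over the floor, so its probe could hardly show a fall.

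Also among these 12 lower genes were Lefty1, an antagonist of Nodal signalling (16.9-fold lower), Cobl, an actin nucleator (14.4-fold), Hspb1, a small heat shock protein (10.0-fold), and Pla2g1b, a secreted phospholipase (at least 9.50-fold). Cldn4 (7.50-fold) and Jam2 (at least 5.42-fold), both of tight junctions, were also lower. The second probe of Jam2 gave a log2 difference of -2.06 against -3.07 for the first, both with an EB signal under the floor. Bead-level standard errors of the 24 genes with the largest differences ran from 0.07 to 0.14 on the log2 scale.

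Stard8 (identifier scl0236920.7_41-S) had signals of 355 in ES and 5689 in EB, a log2 difference of 4.00 with a bead-level standard error of 0.09. Nrp1, a co-receptor for semaphorins and vascular endothelial growth factor, was 12.6-fold higher, and its second probe gave a log2 difference of 3.62 against 3.66 for the first. Lhx1, a homeobox factor of the early embryo, was at least 9.16-fold higher, Unc5c, a netrin receptor, at least 8.08-fold, Hoxb2 at least 7.78-fold and Lmo2, a factor needed for blood formation, at least 6.76-fold. Eomes, a T-box factor of the primitive streak, was 7.06-fold higher, Vldlr, a lipoprotein receptor, 6.62-fold, Klhl6 6.98-fold and Adra2b at least 5.41-fold. Genes with an ES signal under the floor have no fixed rank here: with the values of the series table Unc5c (log2 difference of 6.95) and Lhx1 (6.55) exceeded Stard8. Second probes of Klhl6 and Adra2b lay under the floor in both arrays. Fgf10 was 7.14-fold higher by its brighter probe, and its second probe had a signal of 452 in EB and one under the floor in ES. Peg3, a paternally expressed imprinted gene, was 6.55-fold higher by its brighter probe, and its second probe gave a log2 difference of 2.26 against 2.71.

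**Figure D2:**
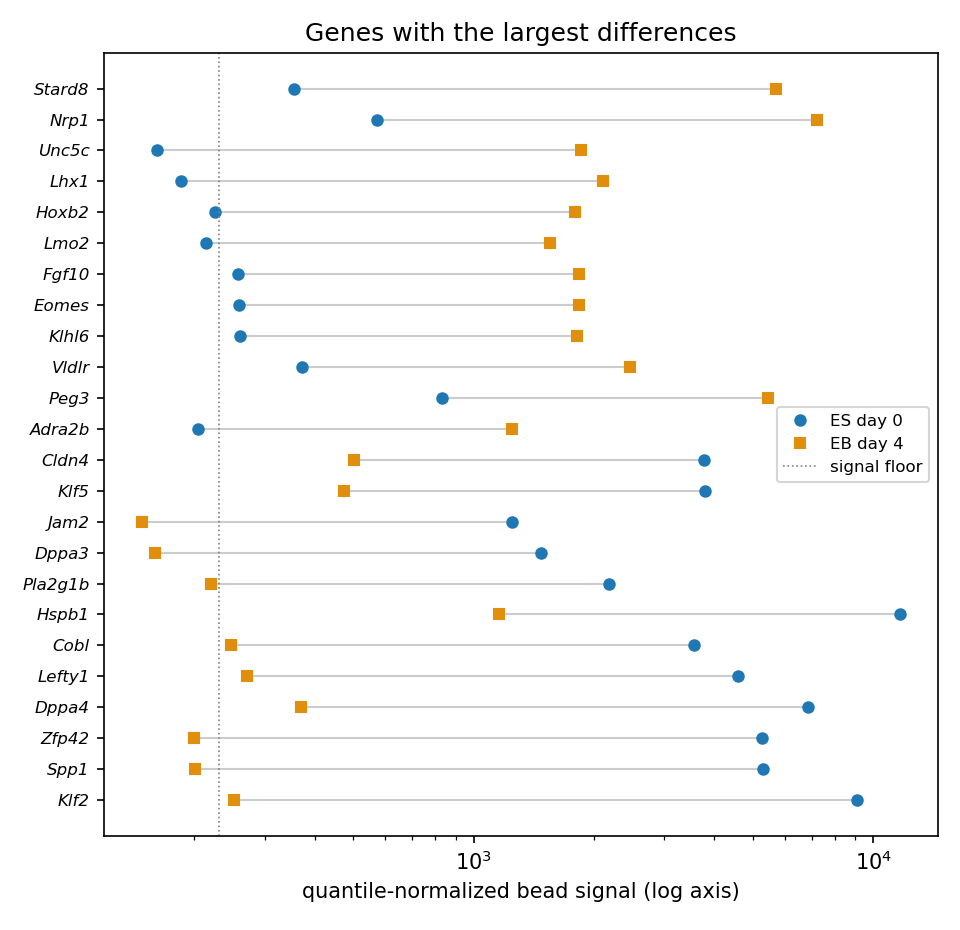
Quantile-normalized bead signal (log axis) in ES day 0 (circles) and EB day 4 (squares) of the 12 genes with the largest measured differences in each direction, 1 array each, without error bars. The dotted line marks the signal floor, under which a signal sets only a bound on the ratio; Stard8 lies at 355 in ES and 5689 in EB, and Klf2 at 9100 and 252.

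Early lineage genes were mostly represented by short lists, which are given as counts. Of 4 detected genes of the primitive streak and nascent mesoderm, 3 were higher (Lhx1, Eomes and Fst, a secreted activin antagonist, 3.95-fold) and 1 was lower (Lefty2, 2.60-fold). Of 4 mesoderm, cardiac and endothelial genes, Lmo2, Wnt5a (at least 3.20-fold) and Myl7, an atrial myosin light chain (3.28-fold), were higher and Pecam1, an endothelial adhesion molecule also made by ES cells, was 2.53-fold lower. Otx2, 4.59-fold higher, was the one of 4 primed epiblast genes past the rule, and Cdh2, which encodes N-cadherin (3.10-fold higher), the one of 3 mesenchymal genes, although the mean over the probes of Cdh2 (0.77), of which 1 was under the floor in both arrays, did not pass. None of 4 detected neural ectoderm genes passed it. Of 9 primitive and visceral endoderm genes Gata4 was higher (at least 1.97-fold) and Trf lower (at least 1.40-fold), with a list median of 0.18 (percentile 85.4). Of 9 trophoblast genes Plac1 (at least 2.36-fold) and Gata3 (2.68-fold) were higher and Tfap2c (5.42-fold) and Krt19 (3.49-fold) lower, with a median of 0.01 (percentile 42.9). The second probe of Tfap2c gave a log2 difference of -0.66, under the size rule. Among 4 germ cell and 2-cell stage genes Tcstv3 was lower (at least 1.88-fold).

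The primitive blood list stood apart, with 3 of 6 detected genes higher and a median log2 difference of 1.07 (percentile 100). They were Hba-x, an embryonic globin (at least 3.26-fold), Hba-a1, an adult alpha globin whose gene has a near-identical copy (at least 2.23-fold), and Nfe2, an erythroid transcription factor (at least 1.82-fold). All 6 members were under the signal floor in ES, and Itga2b and Hbb-b1 were under it in both arrays, so the median rests on differences against background. It was 0.72 with signals set to the floor (percentile 99.98) and 3.35 with the values of the series table, and with a common floor in either array or detection in both samples 4 genes were left, too few for a percentile.

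The cholesterol synthesis list stood apart on the higher side, with a median of 0.79 over 12 detected genes (percentile 100). Of these 3 passed the size rule, 9 did not, and 10 of the 12 differences were positive. Cyp51, the lanosterol demethylase, was 2.92-fold higher, Nsdhl 2.45-fold and Lss, the lanosterol synthase, 2.34-fold. Under the rule were, among others, Hmgcs1 (log2 difference of 0.97) and Fdps (0.94). Srebf2, a regulator of the pathway, gave -0.32 with its first probe and 0.48 with its second, so its probes disagreed.

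**Figure D3:**
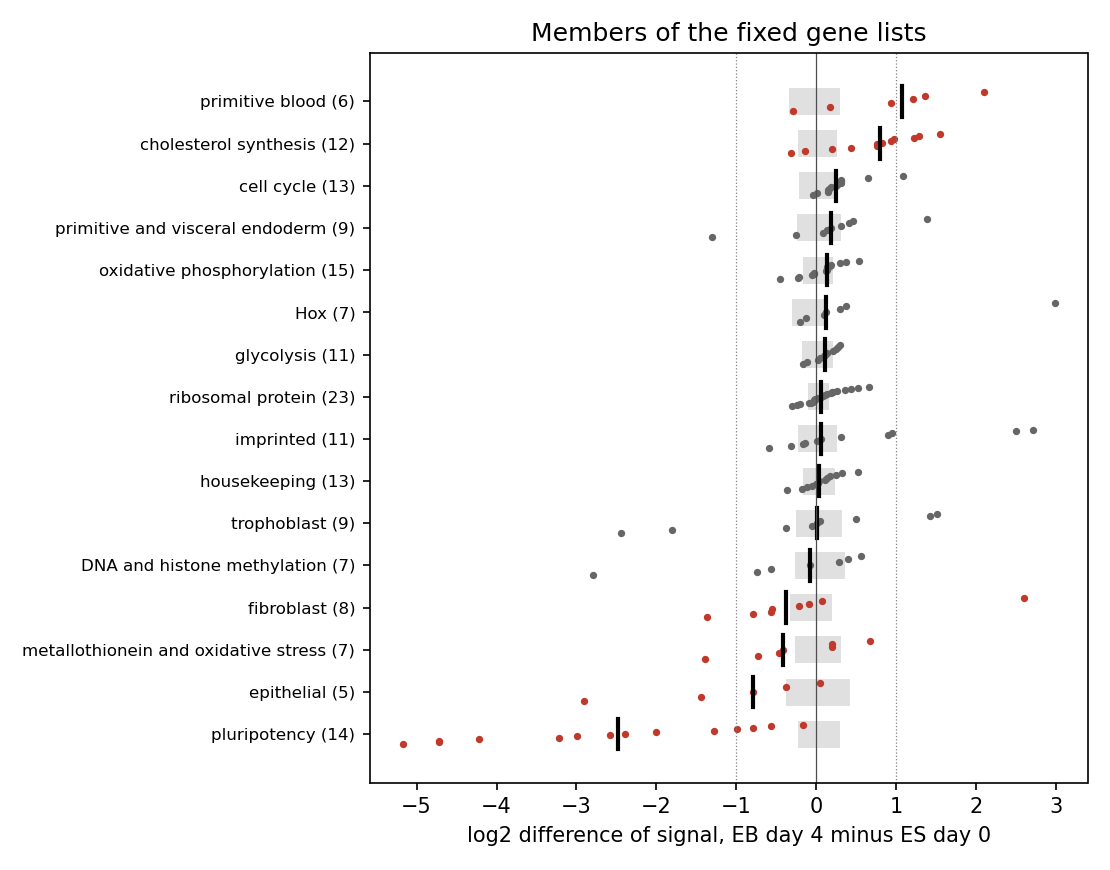
Log2 difference of signal, EB day 4 minus ES day 0, of each detected member (dots) of the 16 lists with at least 5 detected genes (number in parentheses), with the list median (black bar) and the central 95% of medians of matched random lists (grey box). Red dots mark the 6 lists that stood apart, from primitive blood at 1.07 to pluripotency at -2.49, and dotted lines a 2-fold difference.

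Besides pluripotency, 3 lists stood apart on the lower side. The epithelial list had 5 detected genes and a median of -0.79 (percentile 0.19; -1.57 with the values of the series table); 2 of them passed the rule, among them Cldn4, while the keratin Krt8 gave 0.05. The metallothionein and oxidative stress list had a median of -0.41 over 7 genes (percentile 0.39), with Mt1 2.63-fold lower; among genes detected in both samples the median was -0.11 (percentile 12.8), and the list no longer stood apart. Of 8 fibroblast genes Col1a1, a collagen chain, was 2.58-fold lower and Fbln2, an extracellular matrix protein, 6.04-fold higher, with a median of -0.38 (percentile 0.92). That result ended under 5 other settings, among them the series value table (-0.61, percentile 3.15) and the mean in place of the median (-0.11, percentile 38.9). With randomly drawn genes 0.8 of the 16 lists with a percentile would stand apart, and 6 did. Some lists share genes and members of a list can vary together. The 0.8 is therefore not the number to be awaited from 2 samples without a biological difference.

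The remaining lists with a percentile did not stand apart. In the cell cycle list 12 of 13 members had a positive difference and Ccne2, a cyclin of S phase entry, passed the rule by its brighter probe (at least 1.88-fold higher), with a list median of 0.25 (percentile 95.8; 97.6 among random lists not matched on signal). The second probe of Ccne2 was under the floor in both arrays, and the mean of its probes (0.57) did not pass. Hoxb2 was the 1 of 7 detected Hox genes past the rule, with a list median of 0.12 (percentile 96.7); 4 of the 7 were under the signal floor in both arrays. The list stood apart without quantile normalization (median 0.11, percentile 98.9) and by its mean (0.51), but its median was 0 with signals set to the floor (percentile 50) and lay at percentile 78.4 of unmatched random lists. Among 11 imprinted genes Peg3 and Mest (5.64-fold) were higher, with a median of 0.06 (percentile 61.4) and a mean of 0.57 that stood apart. Of 7 genes of DNA and histone methylation Cbx7, a Polycomb protein, was 6.96-fold lower, with a median of -0.08 (percentile 24.9) and a mean of -0.42 that stood apart. No gene passed the rule among 23 ribosomal protein genes (median 0.06, percentile 66.5), 15 of oxidative phosphorylation (0.13, percentile 85.1), 11 of glycolysis (0.11, percentile 80.1) or 13 housekeeping genes (0.04, percentile 48.3). Actb and Gapdh differed by 0.04 and 0.02, with a sign that turned under 1 other setting each.

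Lists of signalling and stress had few detected genes. Of 3 genes of the Nodal pathway Lefty1 and Lefty2 were lower and Tdgf1, just over the floor in both arrays, was under the rule. Of 2 BMP targets Gata3 was higher and Id3 gave 0.97. Of 3 WNT targets Nkd1, a feedback inhibitor, was higher, with a signal of 575 in EB and one under the floor in ES. Of 2 CDK inhibitor and p53 target genes Cdkn1a was 2.44-fold lower. Of 3 hypoxia genes Egln3 was 2.67-fold higher, and of 4 immediate early and stress genes Hspb1 was lower.

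Unnamed probes also differed. The probe scl42945.8.1_35-S had a signal of 14343 in ES and one under the floor in EB, at least 62.4-fold lower, and scl45724.3.1_2-S was at least 24.2-fold lower. In the other direction scl26670.3.10_104-S was 30.3-fold and scl16332.2_164-S 22.6-fold higher. Their genes are not named here.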

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

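The tests in this part were chosen after the results were seen. Control and other probes outside the gene comparison carried signal above the floor in either array: 3 of 3 probes of 18S ribosomal RNA, 12 of 13 probes of the mitochondrial genome, 17 of 78 reverse-complement probes, 1 of 51 T cell receptor probes, 1 of 300 immunoglobulin probes and 1 of 285 probes whose identifier starts with a plain number. Of 22 spike-in and 19 reporter probes 0 did.

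The 18S probes (median log2 difference of -0.46) and the mitochondrial probes above the floor (-0.38, from -1.19 for ND4L to -0.03 for COXIII) all had negative differences, EB minus ES, and so had 3 of 3 small nucleolar RNAs (median -0.65) and 23 of 24 histone probes of the H2B, H3 and H4 clusters (-0.31); most of these RNAs lack a long poly(A) tail, the histone classes were picked out after differences had been tallied over symbol prefixes, and histone copies share sequence, so their probes are not independent. For a trend with brightness or the normalization as a cause, other probes of like signal were examined (the 50 nearest to each of the 50 probes, H2A included). Their median difference was at least 0.0232 under each of 6 scalings, above the upper quartile of the set (-0.18 in the main values). Values that are quantile normalized, or close to it, hold little of such a trend by construction, so only the scaling without that step bears on the question. There the like probes had a median of 0.0457 and the set an upper quartile of -0.14. These values argue against a trend with brightness or quantile normalization as the whole cause. For fewer cells in S phase as a cause of the histone differences, the fixed cell cycle list was examined. It did not fall with the histones (lower quartile 0.14). The list is not limited to genes of S phase and did not stand apart (percentile 95.8), so it cannot settle the share of cells in S phase. A general loss of RNA without a poly(A) tail did not hold for the H2A cluster, where 2 of 8 probes were lower and the median was 0.22 (class medians kept their signs under the scalings), while for the other classes it cannot be told apart from a biological difference between the samples, because they were chosen after their medians (the highest -0.20) were seen. The difference between day 0 and day 4 itself, which the design names, stays open and untested.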

How the results depend on the processing

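The alternatives with a common floor, normexp background or signals set to the floor were chosen after the data were seen; the others were planned. No paired analysis was possible because each group holds 1 sample, and for the same reason no sample or array could be left out. The total of 351 genes past the size rule (144 higher, 207 lower) stayed within 1.5 times under 8 other settings of scaling, background, floor, detection or probe choice (237 to 482). It was unchanged with a common floor in either array, without a detection filter and with a bead-error limit of 2 standard errors. The lower count alone moved by more than 1.5 times with detection, or a common floor, in both samples. The series value table gave 1123 (546 higher, 577 lower), which included all 351; of its 772 further genes 718 were under 4 times the floor, where the table stretches differences. A log2 limit of 2 gave 63 (23 and 40), a 1.5-fold limit 950 (479 and 471) and a limit relative to genes of like brightness 193 (96 and 97), as their construction sets. Detection in both samples left 134 lower genes and 133 higher ones, but its limit is stricter in EB and so drops more lower genes by construction; a common floor in both arrays, even on the 2 sides, left 134 lower and 103 higher. The correlation across genes was 0.928 in the series value table and 0.946 after normexp, against 0.950. No list reversed: 186 alternative list values kept their side of the limits, 8 ended a call and 5 made one. The fibroblast median was -0.61 in the series value table, 0 with signals floored, -0.0501 without a detection filter, -0.56 with a common floor in either array and -0.11 as a mean, and no longer stood apart in any of these. The metallothionein list ended at -0.11 with detection, or a common floor, in both samples and -0.28 as a mean. Newly standing apart were Hox without quantile normalization (0.11), the means of Hox (0.51), imprinted (0.57) and DNA and histone methylation (-0.42), and cell cycle (0.25) against unmatched random lists. Without a detection filter 2 lists otherwise given as counts stood apart, mesoderm, cardiac and endothelial (1.08 over 6 genes) and germ cell and 2-cell stage (-0.33 over 5). Both then took in genes detected in neither sample, and Tcstv1 and Usp17lc of the germ cell list were under the signal floor in both arrays. With a common floor or detection in both samples primitive blood and Hox had too few genes for a percentile. So had DNA and histone methylation with either limit in both samples, and primitive and visceral endoderm with the floor in both. Apart from the stated constructions the cause was not tested. Of 606 alternative differences of 58 named genes 108 moved by over 2 bead-level standard errors and 498 did not. Detection limits and median centring could move none that far. None past the size rule changed sign. Under it Actb (-0.06 as a probe mean) and Gapdh (-0.04 without quantile normalization) did. With signals set to the floor 5 fell under the rule (Ccne2, Gata4, Nfe2, Tcstv3 and Trf), and as a probe mean 2 (Ccne2 at 0.57 and Cdh2 at 0.77). Signal over background limits dim genes: a measured ratio needs both signals above the floor of 230.0.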

Other observations

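The gene groups and tests in this part were chosen after gene values had been seen, and the groups were partly seeded by genes already known to differ, so their percentiles are no independent evidence. Genes of the LIF and STAT3 pathway, through which the cytokine LIF keeps mouse ES cells undifferentiated, were lower in EB: 6 of 9 detected genes passed the size rule, none was higher past it, and the median log2 difference was -1.39 (percentile 0). Stat3 itself was 2.62-fold lower, Klf4 at least 5.87-fold, Bcl3 at least 2.68-fold and Sgk1 2.40-fold. Il6st (-0.16) was under the rule, but its signals of 305 in ES and 274 in EB left little room above the floor for a fall. Lifr, the LIF receptor, was under the signal floor in both arrays. Klf4 and Klf5 also belong to the pluripotency list. Interferon-stimulated genes had a median of -0.69 over 17 genes (percentile 0). Of these 7 were lower past the rule, among them Pml (3.58-fold), Trim25 (2.75-fold) and Oas1a (at least 3.53-fold), and 1 was higher (Ifi27l2a, at least 2.10-fold).

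Genes of cell junctions and keratins had a median of -1.30 over 22 detected genes (percentile 0), with 15 lower and 1 higher. Krt42 was at least 5.05-fold lower, Sfn, an epithelial 14-3-3 protein, 4.29-fold, the desmosomal gene Jup 2.18-fold and the hemidesmosomal gene Plec 2.42-fold. Krt8, the brightest of the group, gave 0.05, and Cgnl1, a junction protein, was 3.09-fold higher. Of these genes 4 also belong to the epithelial list.

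By the main rule 207 genes were lower and 144 higher. Normalization stays open as a cause: in each of 7 scalings lower genes outnumbered higher ones, but with the values of the series table the share of called genes that were higher was 48.6% (exact binomial 95% interval 45.7% to 51.6%, which treats genes as independent). Fibroblasts of a feeder layer in the ES sample, which no label mentions, stay open too: of 14 genes of the fibroblast list 9 were under the signal floor in ES, among them Col1a2, Col3a1 and Dcn, whose probes were above the floor in neither array, while 3 of the 5 above it had a negative difference (Col1a1 with signals of 2602 and 1007, Col5a1 with 1969 and 1335, Acta2 with 419 and 242) and 2 a positive one (Fbln2 and Col6a1). The difference between the cultures stays open and untested.

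The shift of the cholesterol synthesis list (median 0.79) was weighed against a trend with brightness and errors of single probes. Against a trend with brightness, other genes of like signal (the 50 nearest to each member) had a median difference of at most 0.0409 under the 6 scalings tried. That lay below the lower quartile of the list, which was 0.38 in the main values. Values that are quantile normalized, or close to it, hold little of such a trend by construction. Only the scaling without quantile normalization could show it. There the like genes had a median of 0.0326 and the list a lower quartile of 0.39. Against errors of single probes, 6 of 6 second probes above the floor, from 5 genes, were higher in EB, among them both further probes of Nsdhl (1.43 and 1.17) and that of Cyp51 (1.69), although the first probe of Srebf2 was lower. A biological difference in sterol synthesis between these 2 cultures is a hypothesis that stays open, as does a difference in medium or cell density, on which the labels used here give nothing.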
